A study of Helianthus annuus with 6 samples.

How the data were processed

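The series holds 6 samples of sunflower (Helianthus annuus) leaf discs, 3 transformed with 35S::GUS and 3 with 35S::HaHB11. Per the labels' protocols, plants were grown at 25 °C with 16 h of light and 8 h of dark, 100 mg of frozen tissue was used for RNA, and 0.5 µg was labelled with Cy3 for 1-colour Agilent arrays. Groups and replicate numbers were taken from the labels.

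The scanner output of each array gives, per the file headers, a background-subtracted and detrended intensity for each spot, together with the mean and local background intensity and flags for outliers, saturation and signal well above background. The file headers name Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.1. The authors also deposited a table of processed values of the same arrays, on a log2 scale as far as its values show, made by a normalization that is not given in the sources used here. The log2 scale was inferred because its values rose by 0.918 to 0.964 per log2 unit of processed signal. Spearman's rho with that signal was 0.970 to 0.978 per array, which also sets the direction. The medians of its columns were 5.21, 5.22 and 5.25 for control replicates 1, 2 and 3 and 5.22, 5.23 and 5.20 for HaHB11. Its background correction is likewise not given, and it served as an alternative only.

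Control spots were left out, as were spots with an outlier flag (30 to 63 per array). The main values were log2 of the processed signal minus the array's 75th percentile over non-control spots, and spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 17204 probes untested. Groups were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over the 23039 tested probes and a threshold of 0.05. A second count required a change of at least 2-fold. The number of arrays limits the precision of all values.

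The fit was tested on simulated data of the same 23039 probes. With 200 changed probes, 22% of those changed by 1 log2 unit and 76% of those changed by 2 log2 units were called, with 7 calls among 22839 unchanged probes. With as many changed probes as were called in the real comparison, 79.2% and 97.1% were called, with 187 calls (1.05%) among 17779 unchanged probes. The simulated noise was independent between probes and arrays and held no effect of scan day, so these rates may not hold for the real arrays.

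Alternatives were quantile normalization, normexp background correction (offset 50) followed by either scaling, median scaling, no filter on dim probes, a filter on all 6 arrays, trended and robust eBayes, array weights, the authors' table, the replicate number as a block, unadjusted p, and leaving out each array. Scan day as a block, scaling to spike-ins with and without that block, removal of a loess trend on probe GC content (span 0.7) and cyclic loess were added after seeing the data.

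Gene names were sought in the files and in a RefSeq gene table of assembly HanXRQr2.0-SUNRISE with 83308 genes. None of the probe names and 0 of the 74 sequence accessions in the files matched it, and every probe description reads as unknown. The planned gene lists and the check of the HaHB11 and GUS transcripts were therefore not run. The rule for named probes was fixed before the data were examined. Without gene names it allows the 2 probes with the largest rise and the 2 with the largest fall among those past the threshold whose groups do not overlap.

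In place of gene lists, the 3 forward frames of each probe were translated with Biopython 1.88 under Python 3.11.15 and searched for conserved peptides. The first 41 pattern groups were written after the files were opened and before any fold change was computed, and gave 24 forward hits, 0 reverse hits and 0 hits in shuffled probes. A further 23 groups of shorter patterns were written after the number of called probes was known, and gave 35 forward hits, 2 reverse hits and 4 hits in shuffled probes. Every tested probe found is reported by its count, whatever its result. Set tests were camera (correlation 0.01, and estimated) and fry, run on the 1 set with at least 5 tested members. Pairs of probes were compared by shared bases (at least 20), design number and place on the array. Scan days and slides were taken from the files and numbered.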

Results

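Gene expression was measured in sunflower leaf discs that had been transiently transformed with 1 of 2 constructs. In the HaHB11 group the 35S promoter drove HaHB11, a sunflower transcription factor of the homeodomain-leucine zipper family. In the control group the same promoter drove GUS, a bacterial reporter enzyme. Each group held 3 samples, which the series' design text calls biological replicates, and each sample was hybridised to its own 1-colour array. The labels do not say whether the discs of a group came from separate plants, so the p-values measure the spread between these samples. An array read 40243 distinct sunflower probes of 60 nt on 40909 spots. Between 22652 and 24397 probes per array (56.3% to 60.6%) were well above background, and no spot outside the controls was saturated. The 75th percentile of the processed signal lay between 374 and 585 intensity units. Levels are given as log2 of the processed signal relative to that percentile of the same array.

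Arrays of the same construct resembled each other more than arrays of different constructs. Across probes, which are not independent replicates, Pearson's r was 0.978 to 0.990 between control arrays and 0.979 to 0.990 between HaHB11 arrays, against 0.935 to 0.949 between the groups. The first principal component held 68.7% of the variance and separated the groups, with scores of -69.9 to -51.2 for control and 53.0 to 67.0 for HaHB11. The second held 13.1%. The median SD of a probe between arrays of a group was 0.22 log2 units in the controls and 0.21 in the HaHB11 arrays.

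The comparison of the 2 constructs asks which transcripts changed in leaf tissue when HaHB11 was overexpressed. Of 23039 tested probes, 5260 (22.8%) differed at a Benjamini-Hochberg adjusted p under 0.05 in limma. Of these, 2694 were higher and 2566 lower in HaHB11. Falls outnumbered rises in some alternatives, with 3340 higher and 4159 lower in the authors' table, 1626 and 1842 with normexp and the 75th percentile, and 247 and 298 with spike-in scaling. The same held with array weights (5304 higher and 5631 lower), normexp and quantile normalization (2665 and 2799) and median scaling (2589 and 2609). The median change over all tested probes was -0.04 log2 units. The median called rise was 2.06-fold and the median called fall 1.95-fold, and 2250 probes had an adjusted p under 0.01. The 3 values of one group lay entirely above or below those of the other for 9706 probes (42.2%), where a probe with interchangeable arrays gives 10%. Probes share array effects, and some passed the filter through 1 group alone, so that 10% is a rough mark only. The share of called probes was similar from dim to bright probes, at 24.8%, 23.5%, 20.6% and 22.4% in 4 groups of equal size by mean level. The count was 5467, 2523 and 3777 without GUS control replicates 1, 2 and 3, and 3047, 3076 and 5700 without HaHB11 replicates 1, 2 and 3. With arrays scaled to the spike-in controls in place of the 75th percentile, 545 probes were called and the median change of all tested probes was -0.39, and with scan day as a block in that fit 1780 were called and the median was 0.03.

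**Figure D1:**
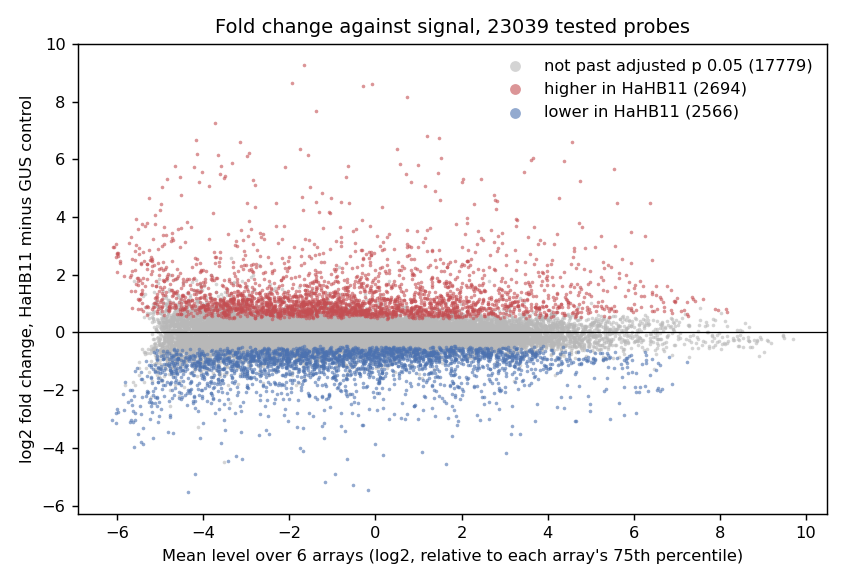
Log2 fold change (HaHB11 minus GUS control, vertical axis) against the mean log2 level over the 6 arrays (horizontal axis), with each point a tested probe. The 2694 probes called higher are red, the 2566 called lower are blue, and called probes lie at every level.

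Among the largest changes there were more rises than falls. At least 2-fold changes among the called probes numbered 1447 up and 1206 down, together 2653. With arrays scaled to the spike-ins 247 rises and 298 falls were called, and with scan day as a block in that fit 1080 and 700. Every call of these fits was at least 2-fold, so the 2-fold cut removed none of them. Their counts are therefore not set at the same effective size as those of the main fit. At 4-fold or more there were 443 rises and 270 falls, at 8-fold or more 179 and 62, and at 16-fold or more 84 and 15. The 16-fold counts were 37 and 3 with normexp and the 75th percentile, 38 and 3 with normexp and quantile normalization, and 75 and 24 with spike-in scaling. These folds are the fitted ones, and those of probes dim in 1 group are uncertain in size.

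Some probes were well above background in 1 group alone. There were 165 probes well above background on all 3 HaHB11 arrays and on no control array, and 156 of them were called higher. The opposite was seen for 114 probes, of which 99 were called lower. For such probes the fold is given as a bound on the processed-signal scale, and another background correction can give a smaller fold. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The median bound was at least 2.20-fold for the HaHB11-only probes and at least 2.19-fold for the control-only probes. A bound of at least 4-fold was reached by 34 HaHB11-only and 8 control-only probes, and a bound of at least 16-fold by 10 and 0.

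The files give a design number and a sequence for each probe and pair none with a gene name, so no probe could be assigned to the introduced HaHB11 transcript. Whether any probe given below reads that transcript is not known. The probes with the largest rises and falls are therefore given by design number and sequence. Probe CUST_14524_PI423492394 (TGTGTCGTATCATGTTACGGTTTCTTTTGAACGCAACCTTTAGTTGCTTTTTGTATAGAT) had a level of -6.30 ± 1.81 (SD, n = 3) in control and 2.96 ± 0.24 in HaHB11. Its fitted log2 fold change was 9.26 (SE 0.78, limma adjusted p 0.00026). Probe CUST_15732_PI423492394 (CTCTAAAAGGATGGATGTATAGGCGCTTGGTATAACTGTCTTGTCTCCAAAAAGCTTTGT) went from -6.27 ± 1.62 to 2.37 ± 0.08, a log2 fold change of 8.64 (SE 0.69, limma adjusted p 0.00022). Both were well above background on 1 of the 3 control arrays and on all 3 HaHB11 arrays, so the size of these folds rests on dim control signals. With the normexp settings the log2 fold change was 5.41 and 5.63 for CUST_14524_PI423492394 and 4.91 and 5.12 for CUST_15732_PI423492394. When 1 array was left out it ranged from 8.60 to 10.29 and from 8.16 to 9.57, with the highest values without GUS control replicate 2. Probe CUST_35950_PI423492394 (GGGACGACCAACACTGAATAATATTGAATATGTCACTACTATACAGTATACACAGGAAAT) was at -1.58 ± 0.56 in control and was not well above background on any HaHB11 array, where it was at least 13.8-fold lower on the processed-signal scale (limma adjusted p 3.8e-05). That bound depends on the background correction, since the fitted log2 fold change of this probe was -5.54 there, -1.79 and -1.53 with the normexp settings and -3.59 in the authors' table. Probe CUST_7685_PI423492394 (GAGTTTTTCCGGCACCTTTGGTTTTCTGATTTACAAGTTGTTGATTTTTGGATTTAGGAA) was measured on all 6 arrays and went from 2.56 ± 0.50 to -2.90 ± 0.61, a log2 fold change of -5.46 (SE 0.36, limma adjusted p 9.7e-05), and of -4.49 and -4.42 with the normexp settings. These 4 probes stayed past the threshold without any 1 array, with adjusted p values up to 0.0018.

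The arrays were scanned on 2 days, with 3 arrays each. Day 1 held 1 control and 2 HaHB11 arrays, and day 2 held 2 control and 1 HaHB11 array, so a fold change was available from separate arrays on each day. Across tested probes the log2 fold changes of the days correlated at r = 0.741 (Spearman 0.599). Of the called probes, 5255 had a value on both days and 5255 had the same sign on both. Of 3231 probes that changed at least 2-fold on day 1, 1791 changed at least 2-fold in the same direction on day 2 and 34 in the opposite direction. Fitted within a day, limma called 3595 probes on day 1 (1896 higher) and 4105 on day 2 (1983 higher) at an adjusted p under 0.05. Each of these fits has 1 group of a single array, which is assumed to vary like the other group, so they do not test the change on each day independently of that assumption. With scan day as a block, 5198 probes were called. A control and a HaHB11 array shared 1 slide, and their difference correlated at r = 0.822 with that of the other 4 arrays. All 5259 called probes with a value there had the same sign on the shared slide. The calls were made on all 6 arrays together, so equal signs among called probes follow in part from their selection.

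**Figure D2:**
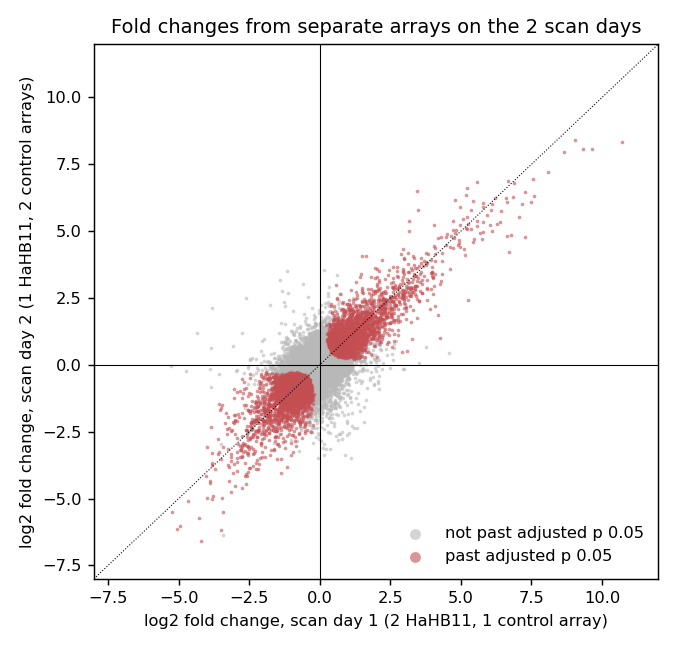
Log2 fold change on scan day 2 (vertical axis) against scan day 1 (horizontal axis) for the tested probes, with probes past adjusted p 0.05 in red and a dotted line of equality. The days share no array and correlate at r = 0.741, and the called probes lie in the 2 quadrants of equal sign.

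The array also carries probes for spike-in control RNAs, and their signals differed between the days. Of 10 spike-in probes 8 were well above background on all arrays, and all 8 were brighter on day 1, by a median of 2.42-fold. The brightest of them hardly differed, with log2 signals of 18.12 to 18.18 on day 1 and 18.04 to 18.12 on day 2. The 75th percentile of the ordinary probes differed by 1.05-fold between the days. To set that percentile against the spike-ins, its log2 value was lowered on each array by the median deviation of the spike-ins from their means over the 6 arrays. The corrected percentile was 9.07 ± 0.73 (SD, n = 3) in control and 8.72 ± 0.85 in HaHB11, a difference of -0.34 (exact two-sided permutation test, p = 0.6, where the smallest p possible is 0.1). Within a scan day the difference between the corrected percentiles was 0.01 on day 1 (control 8.28, HaHB11 8.29) and 0.12 on day 2 (9.46 and 9.58). Each sets 1 array against the mean of 2. The HaHB11 arrays of day 1 lay at 7.87 and 8.72, and the control arrays of day 2 at 9.71 and 9.20. Arrays of the same construct and day thus lay further apart than these differences, which do not show that the constructs are equal.

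**Figure D3:**
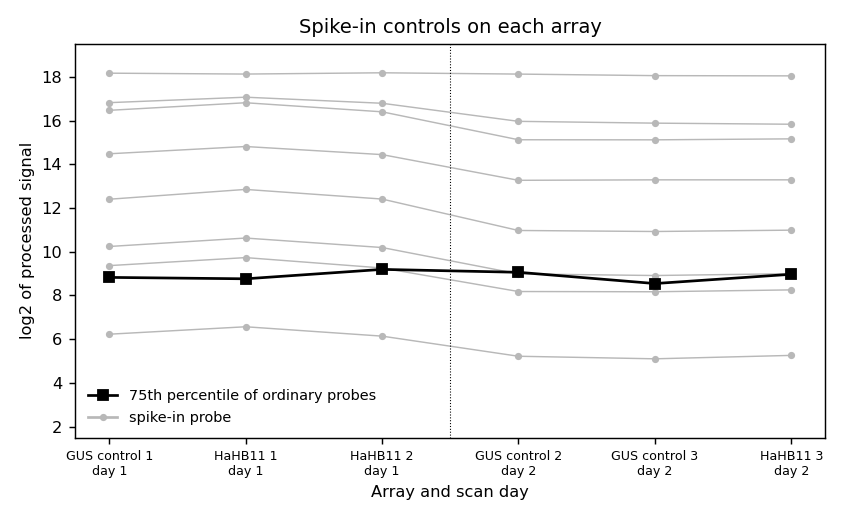
Log2 of the processed signal (vertical axis) of the 8 spike-in probes measured on all arrays (grey) and of the 75th percentile of ordinary probes (black squares) on each array, ordered by scan day (horizontal axis). The spike-ins lie lower on day 2, by a median of 2.42-fold, and the percentile differs by 1.05-fold.

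Some probes could be described by a conserved peptide in the translation of their sequence. The families given are those in which a peptide is commonly found, and a single 60 nt probe does not establish the gene. Of the 24 probes found with the first set of patterns, 19 were tested. Adjusted over all tested probes, 5 were higher and 2 lower, and 7 passed when adjusted over the list alone. The lower ones were the probe with WRKYGQK, the core of WRKY transcription factors, and the probe with AFRVFDKD, found in calmodulins. The WRKYGQK probe went from -0.83 ± 0.40 (SD, n = 3) to -2.32 ± 0.04, a log2 fold change of -1.48 (SE 0.22, limma adjusted p 0.0030). The AFRVFDKD probe went from 5.30 ± 0.34 to 4.24 ± 0.20, a log2 fold change of -1.06 (SE 0.21, limma adjusted p 0.012). Among the higher ones, the probe with QALGGH, found in plant zinc finger proteins, changed by 1.04 (SE 0.20, limma adjusted p 0.0090). The probe with WFQNRRA, from the recognition helix of homeodomains, rose from -0.79 ± 0.25 to -0.01 ± 0.08 (log2 fold change 0.78, SE 0.17, limma adjusted p 0.018), and the files do not say which homeodomain gene it belongs to. The probe with RVTIMPKD, found in histones, changed by 0.82 (SE 0.20, limma adjusted p 0.023).

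Probes with kinase peptides made up the largest group. Of 19 tested, 5 were higher and 14 did not pass, and none was lower in limma, where 22.8% of all tested probes were called. The higher ones included HRDLKPGNLLI at 1.24, HRDLKTSNLLL at 0.89 and a DFGLSK probe at 0.86. The other two, both with DFGLSR at 1.64 and 1.63, overlap in sequence and are not separate evidence. In fits without 1 array, a DFGVAR probe was called lower (-0.63, limma adjusted p 0.041) and the HRDLKPSNLLI probe higher (lowest limma adjusted p 0.032). The median log2 fold change of the 19 was 0.07. As a set they did not shift against the other probes (camera p = 0.261 with a preset correlation of 0.01 between genes, and p = 0.389 with an estimated correlation). In fry, which does not compare the set with other probes, p was 0.0462 for movement in 1 direction and 0.00073 for change in either direction.

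The second set of patterns, which includes part of the kinase peptides, gave 35 probes, of which 29 were tested, 5 were higher and 2 lower. Over that list alone 7 passed, while 22.8% of all tested probes were called. Besides the kinase peptides, leucine-rich repeat probes NRLSGNIP and NRLTGPIP rose by 1.28 and 1.03, while the CAICLGEY probe (RING finger) fell by 0.89 and the GSQFFIT probe (cyclophilin) fell by 0.67, all on the log2 scale. The remaining tested probes of both sets, among them those with ubiquitin, protein disulfide isomerase and 14-3-3 peptides, did not pass. The probe with KIKEKLPG, a dehydrin segment, had levels of 3.50, 3.90 and 0.31 on HaHB11 replicates 1, 2 and 3, against 2.58 ± 0.36 in control. Its log2 fold change was -0.01, and 1.12 without HaHB11 replicate 3. Of the 14 called probes in both sets, 6 stayed past the threshold without any 1 array. The other 8 lost it in at least 1 of the fits without an array, where adjusted p of the 14 reached 0.137. The number lost was 2, 8 and 4 without GUS control replicates 1, 2 and 3, and 8, 8 and 1 without HaHB11 replicates 1, 2 and 3. With all arrays, 8 of the 14 were not past it without a filter on dim probes, 3 with normexp and the 75th percentile, and 1 in the authors' table. With the arrays scaled to the spike-ins none of the 14 was past the threshold in limma, and with scan day as a block in that fit 3 were, the WRKYGQK probe and both DFGLSR probes.

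**Figure D4:**
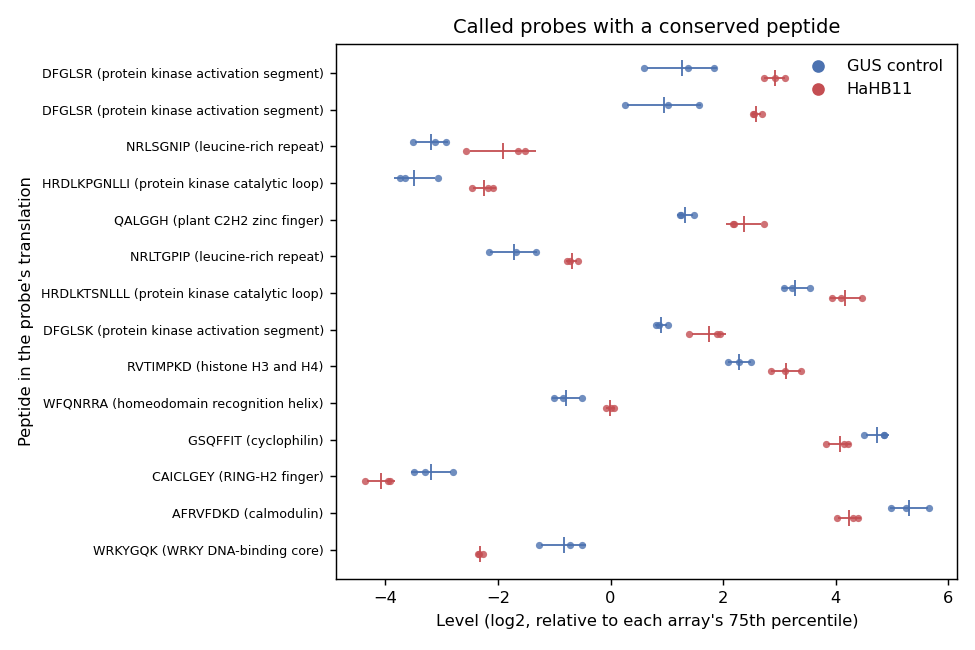
Log2 level relative to each array's 75th percentile (horizontal axis) of the 14 called probes with a conserved peptide (vertical axis), in GUS control (blue) and HaHB11 (red). Points are arrays, ticks are group means and bars are the SD over 3 arrays; the values of the groups do not overlap for any of the 14.

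A set of 74 probes was printed on 10 spots each, which gives the error within an array. The median SD over spots of such a probe was 0.09 log2 units. Of the 50 tested, 11 were called, 5 higher and 6 lower. That share of 22.0% did not differ from the 22.8% of the other probes (Fisher's exact test, two-sided, p = 1).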

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

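Alternatives were chosen before the data were examined, except for scan day as a block, scaling to spike-ins with or without that block, GC trend removal and cyclic loess, which were chosen after the results were seen. The 5260 calls became 3468 with normexp and the 75th percentile, 2807 with no filter on dim probes, 10935 with array weights, 545 with spike-ins, 1780 with spike-ins and the scan day block, and 8616 without adjustment of p. The 2653 calls of at least 2-fold became 1392 with either normexp setting and 545 with spike-ins. Without a filter the adjustment covered 40243 probes. The count at an unadjusted p under 0.05 also went from 8616 to 8443 there, so the adjustment alone does not account for the fewer calls. With array weights, GUS control replicate 2 had a weight of 3.99, against 0.39 to 1.58 for the other arrays. For normexp (5464 calls with quantile scaling) and array weights the cause was not tested. Leaving out 1 array gave from 2523 calls (without GUS control replicate 2) to 5700 (without HaHB11 replicate 3), with 3047 and 3076 without HaHB11 replicates 1 and 2, and from 2110 to 3061 calls of at least 2-fold. The replicate block gave 4222 calls, 4022 of them shared, and left 3 of the 14 called peptide probes short of the threshold; arrays of equal number deviated from their group means with r of -0.03, -0.11 and 0.10, so the numbers were not taken to pair the samples, although pairs 1 and 3 share a scan day. No probe called in both fits changed direction under any alternative. Of 1087 values for 52 single probes, 997 kept their side of the threshold, 71 lost it, 18 gained it and 1 reversed. That was the KIKEKLPG probe, from -0.68 to 1.12 when 1 array was left out, where 1.12 (without HaHB11 replicate 3) had a limma adjusted p of 0.025, against up to 0.945 without another array; the cause was not tested. Slide as a block was not run, since 1 slide alone held more than 1 array and no residual degree of freedom remained. Dim signal kept 17204 of 40243 probes out of the test.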

Other observations

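In this part, the splits of the arrays, and the tests of scan day, spike-in scaling and GC content were chosen only after the number of called probes was seen.

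The 5260 called probes could owe something to technical differences between arrays. With scan day as a block 88.9% of them stayed past the threshold in the same direction, and with the trend on GC content removed 91.4% did, which argues against either as the whole cause. Scaling to the spike-ins kept 10.2% past the threshold, and 31.5% with scan day as a block as well. Without the block the median size of the change went from 1.00 to 1.12 log2 units. The median SD of these probes rose from 0.21 to 0.75 in control and from 0.20 to 0.83 in HaHB11, so calls ended as the spread grew. Relative to the main scaling, spike-in scaling moved every probe of an array by the same amount, the corrected 75th percentile. Its SD was 0.73 in control and 0.85 in HaHB11. It was 8.28 on day 1 and 9.46 on day 2 in control, and 8.29 and 9.58 in HaHB11, so the added spread went in part with scan day. How many probes pass stays open to the choice of scaling. The 6 arrays can be split 3 against 3 in 10 ways, of which 1, the real one, gave as many calls. The highest other gave 0 in limma (88 to 2327 at an unadjusted p under 0.05, the most in the split by scan day). Every other split has arrays of both constructs on each side, so the difference between constructs adds to its spread and lowers its calls. The splits therefore cannot show how many calls chance gives, and 10 splits are too few for a share under 0.05. An effect of HaHB11 itself stays among the open explanations.

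The excess of 16-fold rises (84) over 16-fold falls (15), whose size depends on the processing (37 and 3 with normexp and the 75th percentile, 75 and 24 with spike-in scaling), was set against 4 technical explanations. Among probes whose mean over both groups lay at least 2 log2 units above the floor, 85.3% of such changes were rises (58 against 10, exact 95% interval 74.6% to 92.7%). For changes larger than 16-fold that filter can leave the dim group under the floor, so this share does not decide on the floor. Among probes well above background on all 6 arrays 81.1% were rises (43 against 10, 68.0% to 90.6%), which argues against the signal floor as the whole cause. Both intervals treat probes as independent, which they are not. The lowest share of rises when a HaHB11 array was left out was 81.0%, and scaling to the spike-ins gave 75.8%, where at most 60% had been set as the mark of a single array or of scaling. With probes that share 20 bases counted once, 84.0% were rises (79 against 15), so probes that overlap in sequence do not account for it. Probes at separate places on a transcript share no such bases and were still counted separately. Without gene names, several probes of the same transcript therefore stay possible. Overexpressed HaHB11 may switch a small set of transcripts on more strongly than it turns any off, which is a hypothesis from these arrays that was not itself tested.

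Probes with adjacent design numbers changed together slightly, with r = 0.083 over 13876 pairs against -0.0003 for random pairs. Without pairs that share 12 bases r was 0.082 (bootstrap SE 0.014), so shared sequence is not the cause; the bound of 0.1 set beforehand was wrong, because r over all adjacent pairs already lay under it. Probes in neighbouring spots correlated at 0.0076, and removing the GC trend left 0.083, which argues against place on the array and GC content. Adjacent numbers may come from related transcripts, but no test of that was run.

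Probes on opposite strands of the same sequence were tested for opposite changes, as an antisense transcript that rises when its partner falls would give. The 33 pairs correlated at r = 0.487 (permutation p = 0.0027), with the same direction in 4 of 4 pairs in which both probes were called. For comparison, r was 0.982 for 23 pairs of identical sequence and 0.936 for 992 pairs overlapping on the same strand, where 201 of 201 pairs with both called had the same direction. Opposite changes of the paired probes are therefore argued against for these pairs as a group. Whether the opposite-strand probes read separate antisense transcripts was not tested, so the pairs do not decide how such transcripts are regulated.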
